A study of Danio rerio with 6 samples.

How the data were processed

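RNA was measured in 6 pools of 80 zebrafish larvae, 3 surfactant control and 3 TWP 700 leachate. Per the labels' protocols, RNA with an integrity number over 7.0 was depleted of ribosomal RNA and made into libraries with a stranded total RNA kit. HISAT2, StringTie 2.1.3b, DESeq2 and the genome build GRCz11 are named in the submitters' processing notes, with no role or order given. How reads were summed per gene, and whether strand was used, is not given in the sources used here, so antisense and overlapping genes are uncertain, as are near-identical copies such as the hsp70, opsin, actin and pancreatic enzyme genes.

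Per the file headers, the authors gave read counts, TPM and FPKM for each gene and sample. The deposited counts are whole numbers. The deposited TPM values left out at most 0.0627% of the TPM of a sample. The deposited FPKM values were used with the counts only to derive a relative gene length. The table held 24826 genes, each with a count of at least 1 in each sample. A gene with no read in any 1 sample was therefore not seen, which includes genes switched on or off between the groups. Genes are named by the symbols of the table. Of 1205 symbols written into the gene lists, 1075 matched the table. Coordinates were not used, since the gene table at hand was of another assembly than GRCz11.

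Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, edgeR's expression filter by group, and the robust quasi-likelihood F test of leachate against control, with Benjamini-Hochberg adjustment over the 23761 genes that passed the filter. The SE of a log2 fold change is its size divided by the square root of F. CPM used TMM-scaled library sizes. A count of 3 corresponds to between 0.0619 and 0.081 CPM per sample. Counts per sample were 48431952, 37030725 and 46778228 in control replicates 1 to 3 and 40048977, 42773836 and 37460304 in TWP 700 replicates 1 to 3. Replicates differed by more than sampling noise: chi-square per degree of freedom between libraries of a group was at least 8.53.

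Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 40 lists with at least 5 measured genes. The 41 lists, the test and the naming rule were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a mean CPM of at least 2 and no overlap between groups, leaving out symbols without a gene name, then up to 2 called genes per direction in each list, the 2 most abundant genes of a list with no call, and 10 preset genes as values. The rule named 128 genes, of which 124 were called. Genes named only through a list whose call was lost in 1 or more alternatives are counted in their list but mostly not described, a choice made after the alternatives were seen. A gene that the rule named is not reported here.

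Alternatives were RLE, upper quartile and library total scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of CPM of at least 1 in 3 samples, the robust option off, an adjusted p under 0.01, the replicate number as a block, and each sample left out. Chosen after seeing the data were leaving out control replicate 2 and TWP 700 replicate 1 together, removing a gene length trend from each library, and lists of mitochondrial protein genes, clock phases and fasting genes. Set tests of these added lists were adjusted over the added lists alone. The methods were tested on simulated data of 23761 genes made from the means and library sizes of this comparison. edgeR recovered 34% of genes changed 1.5-fold, 78% at 2-fold, 96% at 4-fold and 98% at 8-fold, each of 50 abundant genes, and called 15 unchanged genes. The simulation changed 200 genes in all, where the real comparison called 3602. Its genes were drawn independently of each other with the dispersions fitted here. The recovery may therefore not carry over to these data.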

Results

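Pools of zebrafish larvae exposed to a tire wear particle (TWP) leachate were compared with pools kept in the surfactant control medium, which held 0.001% bovine serum albumin. No albumin content is recorded for the leachate samples. The leachate group is named TWP 700. The sample titles and the series' design text differ in what the number stands for, a treadwear grade or a concentration, so it is used here as a name. Wild-type embryos were exposed from 4 to 168 h post-fertilization, 200 eggs per dish, with a transfer to clean dishes at 72 h. Each sample was a pool of 80 larvae, and there were 3 samples per group, described as biological replicates. The time of day of collection is not given in the labels. The other leachates that the design text names were not analysed here. RNA depleted of ribosomal RNA was sequenced, and the deposited gene counts summed to between 37030725 (control replicate 2) and 48431952 (control replicate 1) per sample. In pools of larvae a change can come from within cells or from the share of a tissue. Samples are named control 1 to 3 and leachate 1 to 3 by their replicate number, and a list's counts of genes that rose (up) and fell (down) are given again where leaving out samples moved one by over 1.5 times. Levels are CPM as mean ± SD of 3 samples, controls first. Each log2 value is the fold change of leachate over control with its SE, and adjusted p is from edgeR's quasi-likelihood test.

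The design asks which genes differ in larvae exposed to the leachate. The clock genes per1a and nr1d1, the metallothionein gene mt2, the zinc exporter genes slc30a1a and slc30a1b, 15 of 27 sterol synthesis genes and 16 of 30 cell cycle genes were higher in the leachate group. The iron hormone gene hamp, 10 of 25 interferon response genes, 26 of 39 lens genes and 33 of 43 genes of the proteasome list were lower, as were other clock genes such as rorcb. Of 23761 genes tested, 1871 were higher and 1731 were lower, and of these 521 were higher and 334 lower by 2-fold or more. The first principal component held 49.4% of the variance and separated the groups, with the controls between -43.5 and -31.6 and the leachate samples between 34.5 and 41.4. The second held 20.4% and set control 2 (-43.0) apart from controls 1 (16.7) and 3 (31.0). It also set leachate 1 (-17.9) apart from leachate 2 (7.18) and leachate 3 (5.98). In the longest 10% of genes the median log2 deviation from each gene's mean was 0.198 in control 2 and 0.103 in leachate 1. In the other samples it lay between -0.12 and -0.0346. Groups did not overlap in 35.1% of the tested genes, where chance gives 10%. With library totals in place of TMM scaling the median log2 fold change of all genes was 0.131, against -0.0026. The calls then became 2809 higher and 868 lower, 76.4% higher against 51.9%, so directions are given relative to the median gene. Higher and lower calls were 970 and 908 without control 1, 1128 and 896 without leachate 2, and 1123 and 928 without leachate 3.

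The largest rises under the naming rule included per1a and nr1d1, both of the circadian clock. per1a was at 2.3 ± 0.251 against 30.9 ± 9.39 CPM (log2 3.75 ± 0.24, adjusted p = 2.09e-05), and nr1d1 at 3.75 ± 0.718 against 49.2 ± 13.1 CPM (log2 3.71 ± 0.23, adjusted p = 3.26e-05). The metallothionein gene mt2, which encodes a metal-binding protein, was at 96.7 ± 0.735 against 1093 ± 209 CPM (log2 3.5 ± 0.18, adjusted p = 2.94e-06), an 11.3-fold rise. The other 5 were the sterol synthesis gene sqlea (0.658 to 6.26 CPM, log2 3.26), eevs (3.06 to 22.4 CPM, log2 2.88), cfhl2 (0.672 to 4.39 CPM, log2 2.71), the clock gene ciarta (13.4 to 86.1 CPM, log2 2.68) and the zinc exporter gene slc30a1b (0.675 to 4.22 CPM, log2 2.63). Their adjusted p was at most 0.00449, that of eevs. The largest falls were in ifit15 (6.38 to 0.574 CPM, log2 -3.51), nfil3-2 (76.6 to 7.72 CPM, log2 -3.31), nfil3-5 (186 to 20.6 CPM, log2 -3.17), rsad2 (5.6 to 0.622 CPM, log2 -3.16), hamp (32.2 to 3.67 CPM, log2 -3.14), rorcb (53.7 to 6.37 CPM, log2 -3.08), chia.3 (69.3 to 12.9 CPM, log2 -2.42) and cry1bb (69.8 to 15.1 CPM, log2 -2.21). Their adjusted p was at most 0.0116, that of chia.3. ifit15 and rsad2 are interferon-induced, and rorcb, cry1bb and the nfil3 genes belong to the clock or its outputs. The call for ifit15 was lost without control 2 and leachate 1 together (0.0587), and its log2 was -4.48 without leachate 3. For eevs log2 was 3.53 without control 2 and leachate 1 together. Symbols without a gene name were passed over, 16 among the rises and 7 among the falls.

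**Figure D1:**
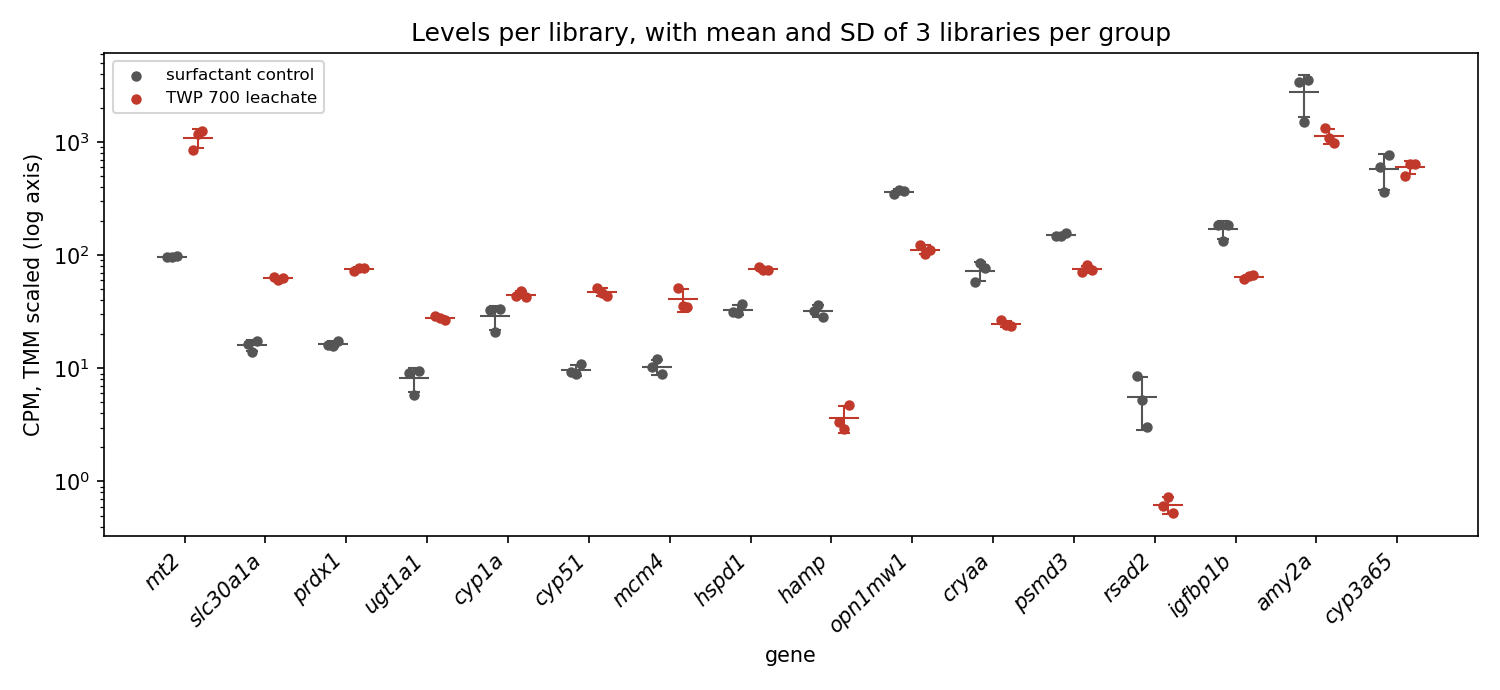
CPM of 16 genes on a log axis, one point per library, with the mean and SD of 3 libraries per group (grey, surfactant control; red, TWP 700 leachate). mt2 stood at 96.7 CPM in the controls and 1093 CPM in the leachate group, and hamp at 32.2 and 3.67 CPM, while cyp3a65 overlapped between the groups.

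Clock genes moved both ways. In the circadian clock list, 14 of 32 measured members rose and 10 fell (14 and 12 adjusted over the list alone). Beside per1a, nr1d1 and ciarta, per1b (17.9 to 78 CPM, log2 2.12), tefa (84.1 to 266 CPM, log2 1.66) and per3 (40.8 to 105 CPM, log2 1.36) rose. rorca (73.7 to 29 CPM, log2 -1.35), clocka (25.8 to 10.8 CPM, log2 -1.26) and arntl1b (32 to 13.6 CPM, log2 -1.24) fell, as did rorcb. tefa, per3, clocka and arntl1b were chosen after their values were seen. The list's median log2 fold change was -0.13 and its mean 0.27, so these differ in sign. That median was -0.0031 with library totals, -0.031 with the stricter filter, -0.22 without control 2, -0.086 without leachate 3 and -0.35 without control 2 and leachate 1 together. As a set the clock genes had a camera adjusted p = 0.00864 (up) and adjusted p = 0.375 with an estimated correlation. The camera call was lost without control 2 (adjusted p = 0.248) and without control 2 and leachate 1 together (0.406). Split by the phase that is usual for each gene, a grouping chosen after the values were seen, 11 of 15 dawn-phase genes lay higher and 10 of 10 dusk-phase genes lay lower.

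**Figure D2:**
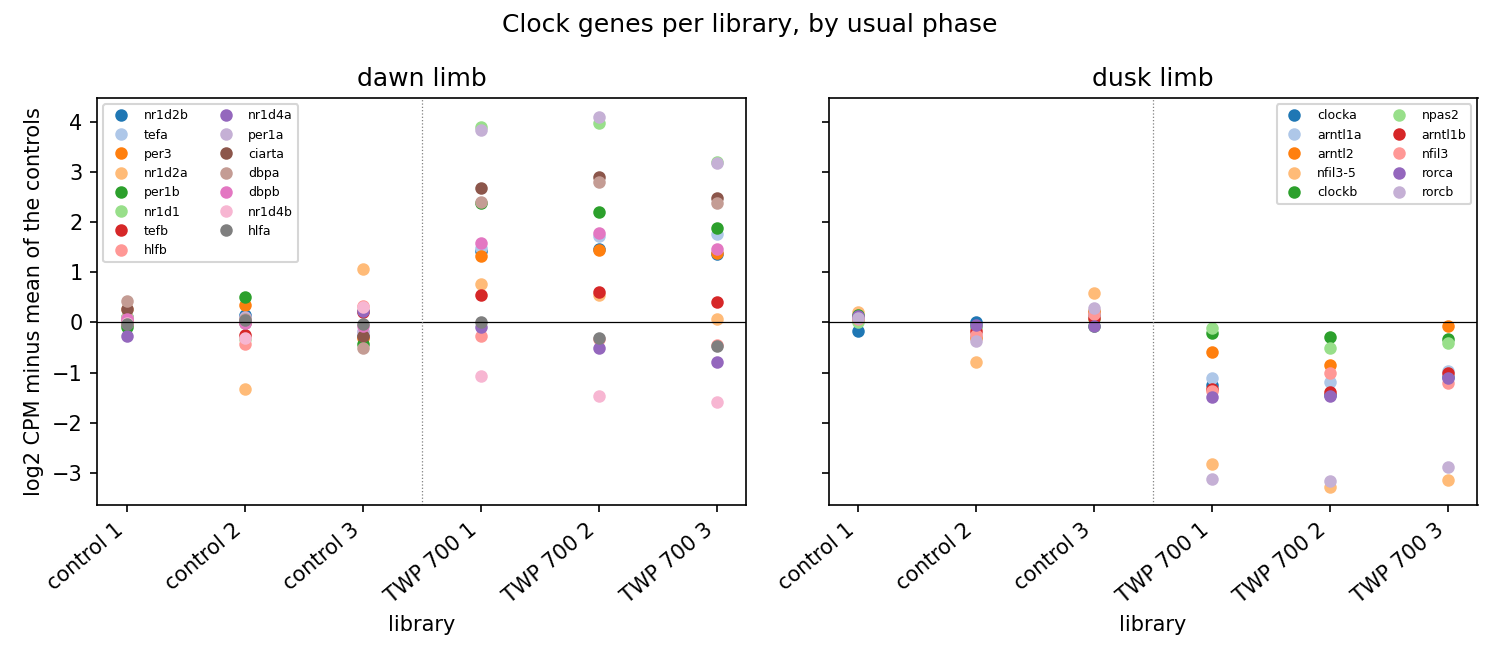
Log2 CPM of clock genes minus the mean of the 3 controls, one point per gene and library, for genes of the dawn phase (left) and the dusk phase (right), a grouping made after the values were seen. The 10 dusk-phase genes lay lower in the leachate group, and 11 of the 15 dawn-phase genes lay higher.

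Genes of metal handling rose in part. In this list, 9 of 23 measured members rose and 1 fell (9 and 4 adjusted over the list alone). The zinc exporter gene slc30a1a was at 15.9 ± 1.81 against 62.7 ± 1.82 CPM (log2 1.98 ± 0.12, adjusted p = 4.17e-06). The transferrin receptor genes tfr1a (19.2 to 58.1 CPM, log2 1.6) and tfr1b (21.5 to 51.8 CPM, log2 1.27), whose products take up iron, also rose, tfr1b being chosen after its value was seen. hamp, which encodes hepcidin, was the member that fell, from 32.2 to 3.67 CPM. Metal handling genes as a set had a camera adjusted p = 3.02e-05 (up) and adjusted p = 0.277 with an estimated correlation. Their counts were 9 up and 3 down without control 2 and 10 up and 3 down without control 2 and leachate 1 together. In the erythroid list, 4 of 21 measured members rose and 1 fell (5 and 1 adjusted over the list alone). tfr1a and the heme synthesis gene alas2 (7.77 to 19.7 CPM, log2 1.34) led the rises. Erythroid genes as a set had a camera adjusted p = 0.0128 (up) and adjusted p = 0.443 with an estimated correlation. Erythroid counts were 2 up and 0 down without control 1, 3 up and 0 down without control 3 or leachate 1, and 4 up and 0 down without leachate 3.

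Of the xenobiotic metabolism and transport genes, 17 of 33 measured members rose and 1 fell (21 and 1 adjusted over the list alone). The glucuronosyltransferase gene ugt1a1 was at 8.14 ± 2.02 against 27.7 ± 1.1 CPM (log2 1.77 ± 0.17, adjusted p = 1.08e-04), and the cytochrome P450 gene cyp2ad2 at 43.3 ± 5.15 against 113 ± 14.9 CPM (log2 1.38 ± 0.14, adjusted p = 1.21e-04). As a set these genes had a camera adjusted p = 2.42e-11 (up) and adjusted p = 0.375 with an estimated correlation. The 1 that fell did not pass without control 1, control 2, control 3, leachate 2 or leachate 3, and 2 fell without control 2 and leachate 1 together. Genes of the aryl hydrocarbon receptor (AhR) list moved both ways. In the AhR list, 4 of 14 measured members rose and 2 fell (4 and 2 adjusted over the list alone), with a camera adjusted p = 0.869. The 2 that fell were the receptor gene ahr1b (16.9 to 11.6 CPM, log2 -0.55) and its partner gene arnt2 (36.3 to 26.8 CPM, log2 -0.44). They belong to the receptor itself and are not its targets, and each passed in 14 of 18 alternatives. The list's median log2 fold change was -0.0016 and its mean 0.094, so these differ in sign. The AhR median ranged from -0.14 (without leachate 1) to 0.095 (without control 3) with 1 sample left out and was 0.14 with library totals. It had the sign of the mean without control 3 and with library totals. cyp1b1 was at 1.82 ± 0.363 against 4.47 ± 0.921 CPM (log2 1.3 ± 0.23, adjusted p = 0.00392). cyp1a, the usual marker of AhR activity, was at 28.9 ± 6.99 against 44.7 ± 3.28 CPM (log2 0.63 ± 0.17, adjusted p = 0.028). Its call was lost without leachate 1 (0.0663), without leachate 2 (0.099) and without leachate 3 (0.0688). The receptor repressor gene ahrra was at 0.546 ± 0.0532 against 1.18 ± 0.375 CPM (log2 1.1 ± 0.34, adjusted p = 0.0488). Its call was lost with upper quartile scaling (0.0518), with the robust option off (0.05), with limma-voom (0.0699), without control 1 (0.114), without control 2 (0.0608), without control 3 (0.117), without leachate 2 (0.191) and without leachate 3 (0.119). AhR list counts were 2 up and 0 down without control 1, 1 up and 0 down without leachate 2, and 1 up and 2 down without leachate 3. They were 4 up and 4 down without control 2 and leachate 1 together. cyp3a65 was at 579 ± 205 against 597 ± 79.2 CPM (log2 0.043 ± 0.24, adjusted p = 0.93) and did not pass the test.

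Oxidative stress genes split. In the Nrf2 and oxidative stress list, 7 of 25 measured members rose and 3 fell (8 and 3 adjusted over the list alone). The peroxiredoxin gene prdx1 was at 16.4 ± 1.01 against 75.3 ± 2.85 CPM (log2 2.2 ± 0.11, adjusted p = 2.16e-06), and the glutathione transferase gene gstp2 at 3.72 ± 1.06 against 14.8 ± 2.16 CPM (log2 1.98 ± 0.2, adjusted p = 1.52e-04). The heme oxygenase gene hmox1a fell and was at 40.2 ± 4.82 against 19.7 ± 0.461 CPM (log2 -1.03 ± 0.12, adjusted p = 2.59e-04), and keap1b (17.8 to 10.1 CPM, log2 -0.82) fell too. Nrf2 genes as a set had a camera adjusted p = 0.00169 (up) and adjusted p = 0.509 with an estimated correlation. Of the heat shock and chaperone genes, 11 of 25 measured members rose and 1 fell (14 and 1 adjusted over the list alone). The mitochondrial chaperonin gene hspd1 was at 33 ± 3.36 against 75.3 ± 2.76 CPM (log2 1.19 ± 0.11, adjusted p = 9.07e-05), and hsp90aa1.2 (30.2 to 64.5 CPM, log2 1.09) rose. Chaperone genes as a set had a camera adjusted p = 1.47e-06 (up) and adjusted p = 0.443 with an estimated correlation. Their counts were 8 up and 0 down without control 1, 10 up and 2 down without control 2, 11 up and 0 down without leachate 2 or leachate 3, and 12 up and 2 down without control 2 and leachate 1 together. hsp70.1 was at 17.7 ± 6.02 against 88.6 ± 76 CPM (log2 2.33 ± 0.74, adjusted p = 0.114) and did not pass the test, with leachate samples at 176, 36.5 and 53.5 CPM. It passed with the robust option off (0.0138), with DESeq2 (0.0109), with limma-voom (0.0191) and without leachate 1 (0.0452, log2 1.35), and log2 was 1.28 without control 2 and leachate 1 together (0.221). In the unfolded protein and integrated stress response list, 8 of 27 measured members rose and 1 fell (9 and 2 adjusted over the list alone). The endoplasmic reticulum chaperone genes calr3b (11.9 to 31.8 CPM, log2 1.42) and dnajb11 (6.64 to 15.5 CPM, log2 1.22) led the rises. This set had a camera adjusted p = 0.00501 (up) and adjusted p = 0.633 with an estimated correlation. Its camera call was lost without control 2 (adjusted p = 0.0672) and without control 2 and leachate 1 together (0.394), and its counts were 6 up and 0 down without control 1, 8 up and 3 down without control 2, 8 up and 0 down without control 3 or leachate 2, 7 up and 0 down without leachate 1, and 8 up and 5 down without control 2 and leachate 1 together.

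Most genes of the proteasome list fell. Of 43 genes that the symbol pattern took, 33 fell and 1 rose (34 and 1 adjusted over the list alone), with a median log2 fold change of -0.58. psmd3 was at 151 ± 6.48 against 75.5 ± 5.4 CPM (log2 -1.0 ± 0.11, adjusted p = 2.88e-04), and psmd11b (58.2 to 29.1 CPM, log2 -1.0) fell. Proteasome genes as a set had a camera adjusted p = 5.05e-16 (down) and adjusted p = 0.375 with an estimated correlation. The gene that rose, psmc3ip, encodes a recombination factor and shares only the start of the symbol. Its call was lost without control 1 (0.114), without control 3 (0.0601), without leachate 2 (0.134) and without leachate 3 (0.0561). Among ribosomal protein genes 84 of 89 lay lower, with a median log2 fold change of -0.27. Of these, 1 passed the test, and 0 did when adjusted over the list alone. The median was -0.14 with library totals, -0.18 without control 3 and -0.16 without leachate 1, and the ribosomal counts were 0 up and 0 down without control 1, control 3, leachate 1 or leachate 2 and 0 up and 6 down without control 2 and leachate 1 together. Ribosomal genes as a set had a camera adjusted p = 7.46e-05 (down) and adjusted p = 0.671 with an estimated correlation. The gene that passed, rps19bp1, does not encode a ribosomal protein, and the pattern also took ribosomal S6 kinase genes. Its call was lost with library totals as the scaling (0.119), without control 1 (0.101), without control 3 (0.059), without leachate 1 (0.0538) and without leachate 2 (0.0981).

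Of 30 cell cycle and DNA replication genes measured, 16 rose and 0 fell (24 and 0 adjusted over the list alone), and the median log2 fold change was 0.88. The replication licensing genes mcm4, at 10.4 ± 1.59 against 40.7 ± 9.2 CPM (log2 1.97 ± 0.17, adjusted p = 7.92e-05), and mcm6, at 6.89 ± 1.79 against 26.8 ± 5.38 CPM (log2 1.97 ± 0.2, adjusted p = 2.23e-04), led the list. Cell cycle genes as a set had a camera adjusted p = 4.47e-20 (up) and adjusted p = 0.375 with an estimated correlation. The number of these that rose was 25 without control 2 and leachate 1 together. In the histone list, 5 of 17 measured members rose and 0 fell (6 and 1 adjusted over the list alone), with a camera adjusted p = 0.053. The histone list passed camera with library totals (adjusted p = 0.0389), without control 3 (0.0412), without leachate 2 (0.029) and without leachate 3 (0.018). Among its members h2afx (15.1 to 29.3 CPM, log2 0.96) rose, and histone counts were 1 up and 0 down without control 1, 7 up and 1 down without control 2, 2 up and 0 down without leachate 1 or leachate 2, 3 up and 0 down without leachate 3, and 7 up and 2 down without control 2 and leachate 1 together. In the p53 and apoptosis list, 3 of 29 measured members rose and 5 fell (4 and 7 adjusted over the list alone). The set had a camera adjusted p = 0.688, and its median of 0.066 and mean of -0.013 differ in sign. The p53 median ranged from -0.07 (without leachate 1) to 0.081 (without control 3) with 1 sample left out, was 0.20 with library totals and -0.096 without control 2 and leachate 1 together. Median and mean had the same sign with library totals, without any 1 sample other than leachate 3, and without control 2 and leachate 1 together. Among its members tnfrsf1a (17.9 to 33.3 CPM, log2 0.89) rose and sesn1 (847 to 433 CPM, log2 -0.97) fell. The p53 counts were 1 up and 1 down without control 1, 3 up and 9 down without control 2, 2 up and 2 down without leachate 2, 2 up and 3 down without leachate 3, and 3 up and 10 down without control 2 and leachate 1 together.

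Of the sterol biosynthesis genes, 15 of 27 measured members rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 0.56. cyp51, a lanosterol demethylase gene, was at 9.68 ± 1.12 against 47.3 ± 3.79 CPM (log2 2.29 ± 0.12, adjusted p = 2.94e-06). The squalene epoxidase gene sqlea rose from 0.658 to 6.26 CPM. Sterol genes as a set had a camera adjusted p = 1.32e-19 (up) and adjusted p = 0.216 with an estimated correlation. Their counts were 18 up and 1 down without control 2 and leachate 1 together. In the list of fatty acid synthesis and lipid storage, 7 of 24 measured members rose and 3 fell (7 and 4 adjusted over the list alone), with a camera adjusted p = 0.141. The elongase and desaturase genes elovl2 (4.15 to 11.9 CPM, log2 1.51) and fads2 (8.33 to 17 CPM, log2 1.03) rose, while srebf1 (37.4 to 22.5 CPM, log2 -0.73) fell. Fatty acid synthesis counts were 4 up and 1 down without control 1, 6 up and 6 down without control 2, 5 up and 1 down without control 3, leachate 2 or leachate 3, and 9 up and 6 down without control 2 and leachate 1 together. In the list of fatty acid oxidation, 10 of 36 measured members rose and 1 fell (12 and 1 adjusted over the list alone). There cpt2 (5.29 to 10.4 CPM, log2 0.97) rose, and the uncoupling protein gene ucp1 (1304 to 728 CPM, log2 -0.84) fell. Fatty acid oxidation genes as a set had a camera adjusted p = 0.00314 (up) and adjusted p = 0.443 with an estimated correlation. The count of these that rose was 6 without control 1.

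In the glycolysis and gluconeogenesis list, 10 of 34 measured members rose and 1 fell (15 and 3 adjusted over the list alone). There pfkma (64.3 to 127 CPM, log2 0.99) and pck2 (63.9 to 108 CPM, log2 0.75) rose and fbp1a (124 to 76.4 CPM, log2 -0.7) fell. Glycolysis genes as a set had a camera adjusted p = 0.0334 (up) and adjusted p = 0.633 with an estimated correlation. That camera call was lost with the stricter filter (adjusted p = 0.0655), without control 1 (0.0543), without control 2 (0.248), without leachate 3 (0.0533) and without control 2 and leachate 1 together (0.225). Glycolysis counts were 4 up and 1 down without control 1, leachate 1 or leachate 3, 7 up and 7 down without control 2, 6 up and 1 down without control 3, 8 up and 2 down without leachate 2, and 12 up and 7 down without control 2 and leachate 1 together. Of the nuclear genes of oxidative phosphorylation, 2 of 32 measured members rose and 0 fell (1 and 0 adjusted over the list alone), with a camera adjusted p = 0.0851. The list passed camera with library totals (adjusted p = 0.0318), without control 3 (0.00568) and without leachate 1 (0.0419), and its counts were 1 up and 0 down without control 1, leachate 1, leachate 2 or leachate 3, 2 up and 1 down without control 2, and 7 up and 1 down without control 2 and leachate 1 together. The cytochrome c gene cycsb (88.3 to 161 CPM, log2 0.86) led it. The 2 mitochondrial ribosomal RNA genes did not pass the test: mt-rnr2 was at 8039 ± 586 against 7886 ± 2726 CPM (log2 -0.028 ± 0.24, adjusted p = 0.955) and mt-rnr1 at 709 ± 70.7 against 642 ± 339 CPM (log2 -0.14 ± 0.32, adjusted p = 0.816). mt-rnr1 fell without leachate 1 (log2 -0.66, adjusted p = 0.0253) and without control 2 and leachate 1 together (log2 -0.70, adjusted p = 0.00105). Its levels were 1029, 499 and 398 CPM in leachate 1 to 3. The libraries were depleted of ribosomal RNA, so levels of these 2 genes may also reflect how much was left in each library.

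Lens genes lay lower, and photoreceptor genes moved both ways. In the lens list 39 of 39 measured members lay lower and 26 fell (34 adjusted over the list alone), with a median log2 fold change of -0.75. The crystallin genes cryaa, at 73.2 ± 14.4 against 24.8 ± 1.66 CPM (log2 -1.56 ± 0.15, adjusted p = 9.07e-05), and crygn1, at 32.3 ± 5.85 against 10.5 ± 1.55 CPM (log2 -1.61 ± 0.16, adjusted p = 1.11e-04), led the list. Lens genes as a set had a camera adjusted p = 3.67e-19 (down) and adjusted p = 0.443 with an estimated correlation. That correlation was 0.67, so the 39 genes are not 39 separate measurements. The number that fell was 9 without leachate 3, and the median was -0.48 without control 2 and leachate 1 together. In the photoreceptor list, 4 of 40 measured members rose and 18 fell (8 and 19 adjusted over the list alone). The cone opsin gene opn1mw1 was at 364 ± 17.5 against 112 ± 9.99 CPM (log2 -1.7 ± 0.13, adjusted p = 2.79e-05), and opn1lw1 at 32.5 ± 2.35 against 10.9 ± 0.613 CPM (log2 -1.57 ± 0.11, adjusted p = 2.00e-05). Both have near-identical tandem copies, so the split of reads between copies is uncertain. The cone arrestin gene arr3b (36.9 to 71.4 CPM, log2 0.95) and the cone phosphodiesterase gene pde6c (115 to 221 CPM, log2 0.94) rose. Photoreceptor genes as a set had a camera adjusted p = 2.90e-06 (down) and adjusted p = 0.375 with an estimated correlation. The count that rose was 7 without control 2 and 9 without control 2 and leachate 1 together.

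**Figure D3:**
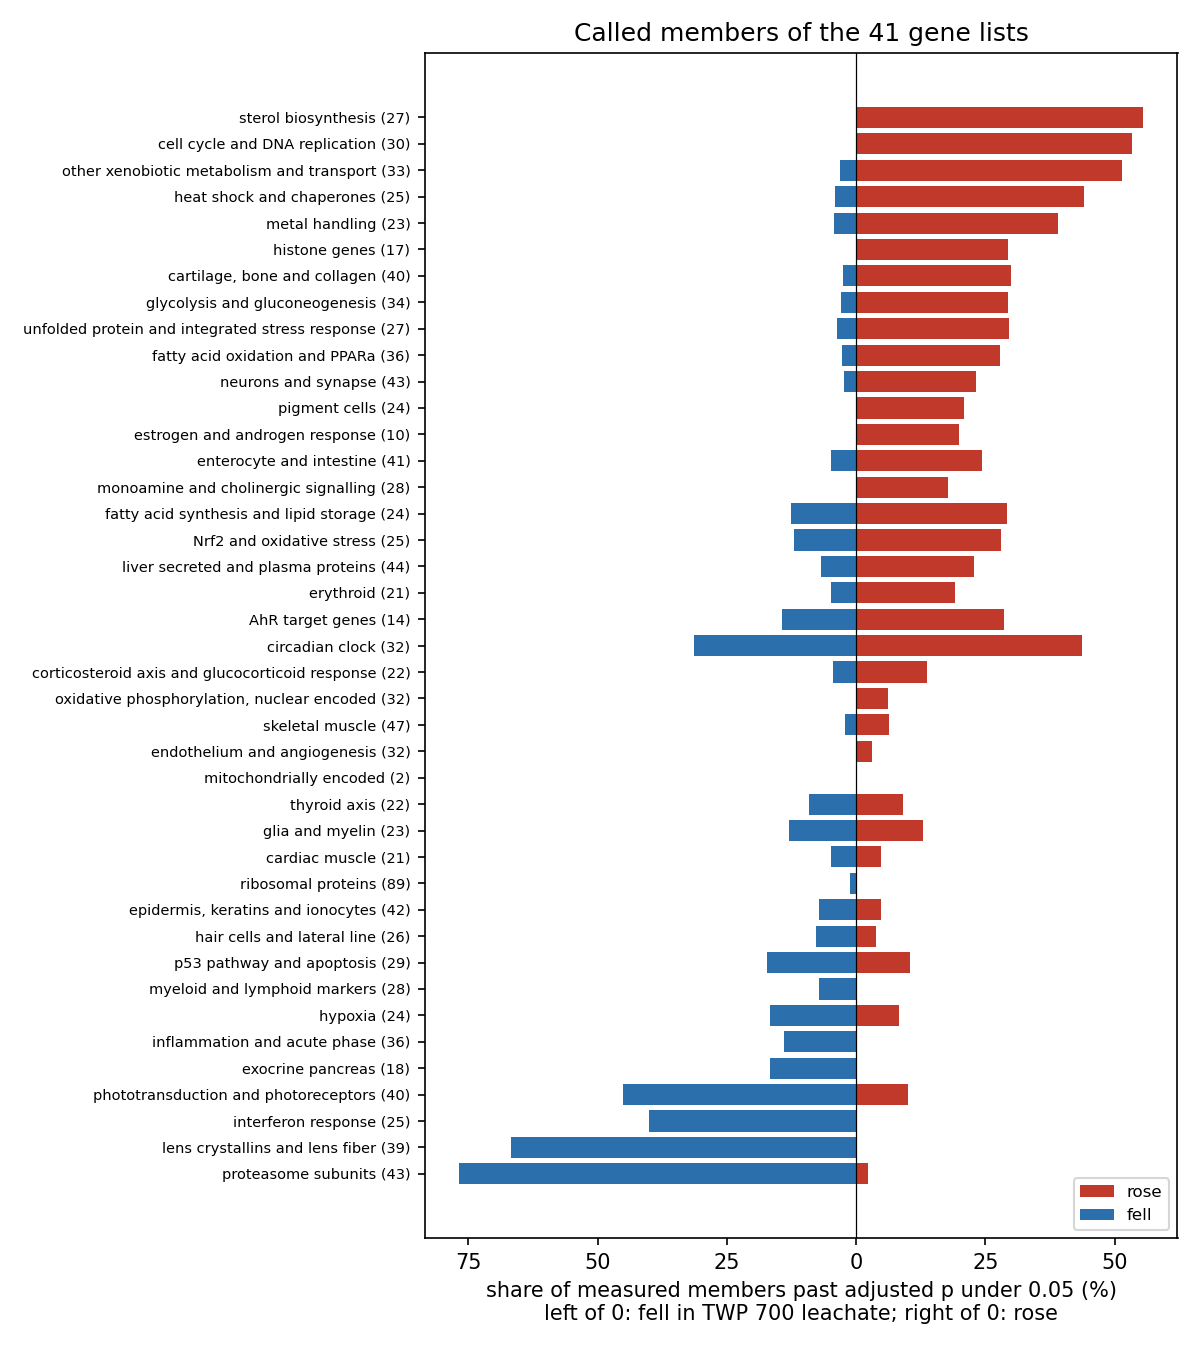
Share of the measured members of each of the 41 gene lists that rose (red, right) or fell (blue, left) at an adjusted p under 0.05, with the number measured in brackets. Sterol biosynthesis (15 of 27 rose) stands at the top, and proteasome subunits (33 of 43 fell) at the bottom.

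In the list of neurons and synapse, 10 of 43 measured members rose and 1 fell (13 and 1 adjusted over the list alone). The tubulin gene tubb5 (32 to 60.3 CPM, log2 0.91) rose, and the transcription factor gene neurod1 fell and was at 137 ± 16.3 against 55.4 ± 5.68 CPM (log2 -1.3 ± 0.13, adjusted p = 1.42e-04). Neuronal genes as a set had a camera adjusted p = 0.0074 (up) and adjusted p = 0.633 with an estimated correlation. That camera call was lost without leachate 1 (adjusted p = 0.104) and without control 2 and leachate 1 together (0.2), and the neuronal counts were 3 up and 1 down without control 1, leachate 1 or leachate 3 and 4 up and 1 down without control 3. Of the monoamine and cholinergic genes, 5 of 28 measured members rose and 0 fell (5 and 0 adjusted over the list alone), with a camera adjusted p = 0.349. The monoamine oxidase gene mao (34.4 to 81.2 CPM, log2 1.24) and ddc (5.97 to 12.8 CPM, log2 1.09) led the rises, and the count was 3 without control 1 and 2 without leachate 2. The acetylcholinesterase gene ache was at 118 ± 10.1 against 168 ± 24.8 CPM (log2 0.51 ± 0.14, adjusted p = 0.0294). The ache call was lost without control 1 (0.105), without control 3 (0.087), without leachate 1 (0.081) and without leachate 2 (0.0765). In the glia and myelin list, 3 of 23 measured members rose and 3 fell (5 and 4 adjusted over the list alone), with a camera adjusted p = 0.499. The myelin genes plp1b (46 to 23.9 CPM, log2 -0.94) and mpz (11.6 to 5.71 CPM, log2 -1.02) fell and slc1a3b (29.1 to 45.4 CPM, log2 0.64) rose. mbpa, which encodes myelin basic protein, was at 225 ± 6.19 against 156 ± 14.1 CPM (log2 -0.53 ± 0.12, adjusted p = 0.0159). The mbpa call was lost without control 1 (0.0591) and without leachate 3 (0.0681). Glial counts were 1 up and 2 down without control 1 or leachate 3, 5 up and 3 down without control 2, 1 up and 3 down without control 3 or leachate 2, and 5 up and 4 down without control 2 and leachate 1 together.

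Of the hair cell genes, 1 of 26 measured members rose and 2 fell (1 and 2 adjusted over the list alone), with a camera adjusted p = 0.362. The parvalbumin gene pvalb9 (25.8 to 54 CPM, log2 1.06) rose and pvalb8 (126 to 58.2 CPM, log2 -1.12) fell. Hair cell counts were 1 up and 1 down without control 1, control 3, leachate 1, leachate 2 or leachate 3. In skeletal muscle, 3 of 47 measured members rose and 1 fell (3 and 1 adjusted over the list alone), with a camera adjusted p = 0.228. There casq1a (33 to 59.7 CPM, log2 0.85) and acta1b (486 to 930 CPM, log2 0.94) rose and mybpc2b (121 to 68.6 CPM, log2 -0.81) fell. Skeletal muscle counts were 3 up and 2 down without control 2, 2 up and 2 down without leachate 1, and 4 up and 7 down without control 2 and leachate 1 together. In cardiac muscle, 1 of 21 measured members rose and 1 fell (3 and 3 adjusted over the list alone), with a camera adjusted p = 0.499. The gene that rose was ryr2a (22.7 to 33.1 CPM, log2 0.54). Cardiac counts were 1 up and 2 down without control 1, control 2 or control 3, 2 up and 1 down without leachate 1, and 2 up and 6 down without control 2 and leachate 1 together.

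Counts of digestive and pigment genes moved with single samples. In the exocrine pancreas list, 0 of 18 measured members rose and 3 fell (0 and 8 adjusted over the list alone). The number that fell was 16 without control 2, and also without control 2 and leachate 1 together. It was 0 without control 1 or without any 1 of the leachate samples, and 1 without control 3. The amylase gene amy2a was at 2790 ± 1124 against 1132 ± 179 CPM (log2 -1.3 ± 0.3, adjusted p = 0.0175). Its call was lost without control 1 (0.0668), without control 3 (0.0502), without leachate 1 (0.0677), without leachate 2 (0.0743) and without leachate 3 (0.0757). Pancreas genes as a set had a camera adjusted p = 9.26e-04 (down) and adjusted p = 0.633 with an estimated correlation. In the pigment cell list, 5 of 24 measured members rose and 0 fell (7 and 0 adjusted over the list alone). There pnp4a (10.4 to 23.5 CPM, log2 1.18) and gch2 (7.67 to 38 CPM, log2 2.31) rose. Pigment genes as a set had a camera adjusted p = 4.68e-05 (up) and adjusted p = 0.443 with an estimated correlation. Pigment gene counts were 12 up and 0 down without control 2, 5 up and 1 down without leachate 1, 3 up and 0 down without leachate 2, and 13 up and 3 down without control 2 and leachate 1 together. In the enterocyte list, 10 of 41 measured members rose and 2 fell (11 and 2 adjusted over the list alone). The lipid transport gene apoa4a was at 1.81 ± 0.306 against 9.56 ± 0.758 CPM (log2 2.39 ± 0.18, adjusted p = 2.09e-05), and agr2 (14.2 to 44 CPM, log2 1.63) rose, while the chitinase gene chia.3 fell. Enterocyte genes as a set had a camera adjusted p = 3.02e-05 (up) and adjusted p = 0.617 with an estimated correlation. Their counts were 9 up and 1 down without control 1, 7 up and 1 down without leachate 2, and 8 up and 1 down without leachate 3. Of the liver genes, 10 of 44 measured members rose and 3 fell (12 and 10 adjusted over the list alone), with a camera adjusted p = 0.487. The median of -0.057 and mean of 0.12 differ in sign. The liver median ranged from -0.175 (without control 2) to 0.028 (without leachate 3) with 1 sample left out, was 0.089 with library totals and -0.17 without control 2 and leachate 1 together. Both were above 0 without control 3, without leachate 3 and with library totals, and both were below 0 without control 2 and leachate 1 together. The heme scavenger gene hpx was at 1.58 ± 0.449 against 9.2 ± 0.833 CPM (log2 2.53 ± 0.21, adjusted p = 4.50e-05), igfbp2a (21.2 to 36.5 CPM, log2 0.79) rose and ahsg2 (59.8 to 26.9 CPM, log2 -1.16) fell. Liver gene counts were 5 up and 1 down without control 1, 7 up and 13 down without control 2, 10 up and 1 down without control 3, 7 up and 7 down without leachate 1, 6 up and 1 down without leachate 2, 9 up and 1 down without leachate 3, and 13 up and 17 down without control 2 and leachate 1 together.

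Of the interferon response genes, 0 of 25 measured members rose and 10 fell (2 and 11 adjusted over the list alone). isg15 was at 7.91 ± 0.606 against 3.11 ± 0.0898 CPM (log2 -1.35 ± 0.15, adjusted p = 2.61e-04), and rsad2 at 5.6 ± 2.76 against 0.622 ± 0.105 CPM (log2 -3.16 ± 0.38, adjusted p = 6.42e-04). Interferon genes as a set had a camera adjusted p = 1.63e-04 (down) and adjusted p = 0.216 with an estimated correlation. Interferon gene counts were 1 up and 11 down without control 2, 0 up and 6 down without control 3 or leachate 3, 1 up and 9 down without leachate 1, and 2 up and 11 down without control 2 and leachate 1 together. In the inflammation and acute phase list, 0 of 36 measured members rose and 5 fell (0 and 5 adjusted over the list alone), led by hamp. Inflammation genes as a set had a camera adjusted p = 0.0287 (down) and adjusted p = 0.633 with an estimated correlation. That camera call was lost without control 3 (adjusted p = 0.0824), without leachate 2 (0.0686) and without leachate 3 (0.0912). Inflammation counts were 0 up and 8 down without control 2, 0 up and 3 down without leachate 2, 1 up and 3 down without leachate 3, and 0 up and 15 down without control 2 and leachate 1 together. Of the myeloid and lymphoid markers, 0 of 28 measured members rose and 2 fell (0 and 2 adjusted over the list alone), with a camera adjusted p = 0.499. The recombinase gene rag1 (12.3 to 6.28 CPM, log2 -0.97) was one that fell. Myeloid and lymphoid counts were 0 up and 1 down without control 1, leachate 1 or leachate 2, 1 up and 1 down without control 3, and 0 up and 4 down without control 2 and leachate 1 together.

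In the cartilage, bone and collagen list, 12 of 40 measured members rose and 1 fell (19 and 1 adjusted over the list alone). The cartilage collagen gene col9a1b was at 14.8 ± 1.81 against 45.4 ± 9.92 CPM (log2 1.61 ± 0.16, adjusted p = 1.42e-04), matn1 (61.7 to 113 CPM, log2 0.88) rose and spp1 (38.1 to 13 CPM, log2 -1.56) fell. Skeletal tissue genes as a set had a camera adjusted p = 1.40e-05 (up) and adjusted p = 0.617 with an estimated correlation. Skeletal tissue counts were 6 up and 1 down without control 1, 19 up and 1 down without control 2, and 22 up and 3 down without control 2 and leachate 1 together. Of the epidermal genes, 2 of 42 measured members rose and 3 fell (2 and 3 adjusted over the list alone), with a camera adjusted p = 0.28. The calcium channel gene trpv6 (16.5 to 44.4 CPM, log2 1.43) and the carbonic anhydrase gene ca2 (98.6 to 151 CPM, log2 0.62) rose, and cyt1l (2988 to 1451 CPM, log2 -1.04) fell. Epidermal counts were 4 up and 4 down without control 2, 2 up and 1 down without leachate 3, and 8 up and 8 down without control 2 and leachate 1 together. Of the endothelial genes, 1 of 32 measured members rose and 0 fell (0 and 0 adjusted over the list alone), with a camera adjusted p = 0.487. Endothelial counts were 0 up and 0 down without control 1, control 3, leachate 1 or leachate 3, 1 up and 1 down without control 2, and 2 up and 2 down without control 2 and leachate 1 together.

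Of the hypoxia genes, 2 of 24 measured members rose and 4 fell (2 and 4 adjusted over the list alone), with a camera adjusted p = 0.502. The median of 0.029 and mean of -0.04 differ in sign. The hypoxia median ranged from -0.032 (without control 2) to 0.066 (without leachate 1) with 1 sample left out, was 0.17 with library totals, -0.023 with the stricter filter and -0.045 without control 2 and leachate 1 together. Both had the same sign with library totals, with the stricter filter, without any 1 of the controls, and without control 2 and leachate 1 together. The hydroxylase gene egln3 (1.39 to 3.06 CPM, log2 1.13) rose. igfbp1b, which encodes an insulin-like growth factor binding protein, fell and was at 169 ± 29.6 against 64.5 ± 2.85 CPM (log2 -1.39 ± 0.14, adjusted p = 1.57e-04), and bnip3 (62.8 to 32 CPM, log2 -0.97) fell too. The hypoxia list passed camera without control 2 and leachate 1 together (adjusted p = 0.0364), and its counts were 2 up and 2 down without control 1, 4 up and 6 down without control 2, 1 up and 3 down without leachate 2 or leachate 3, and 4 up and 7 down without control 2 and leachate 1 together. Of the thyroid axis genes, 2 of 22 measured members rose and 2 fell (2 and 2 adjusted over the list alone), with a camera adjusted p = 0.541. ugt1a1, also in the xenobiotic list, and the deiodinase gene dio1 (9.44 to 20 CPM, log2 1.08) rose, and the oxidase gene duox (2.58 to 0.778 CPM, log2 -1.73) fell. Thyroid axis counts were 2 up and 1 down without leachate 3. In the corticosteroid list, 3 of 22 measured members rose and 1 fell (3 and 1 adjusted over the list alone), with a camera adjusted p = 0.0584. The clock genes per1a and per1b were among those that rose, and the receptor gene nr3c2 (20.8 to 11.4 CPM, log2 -0.87) fell. This list passed camera without control 3 (adjusted p = 0.00492) and without leachate 3 (0.0036), and its counts were 3 up and 3 down without control 2 and 4 up and 6 down without control 2 and leachate 1 together. In the estrogen and androgen list, 2 of 10 measured members rose and 0 fell (2 and 0 adjusted over the list alone), with a camera adjusted p = 0.0949. The brain aromatase gene cyp19a1b was at 0.467 ± 0.131 against 1.72 ± 0.308 CPM (log2 1.88 ± 0.32, adjusted p = 0.00288). Estrogen and androgen counts were 1 up and 0 down without control 1, control 2, leachate 1, leachate 2 or leachate 3. The gene vtg1 was not analysed here.

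Of 40 lists with a set test, 22 passed camera with its preset correlation, 15 up and 7 down. With an estimated correlation camera passed 0 lists, and 3 had an unadjusted p under 0.05. The lowest adjusted p was 0.216. By fry, which asks whether a list's genes move on balance one way, 15 lists passed. Passing camera but not fry were the unfolded protein (fry adjusted p = 0.12), neuron (0.12), pancreas (0.25) and enterocyte (0.11) lists. The same held for the glycolysis (0.11), inflammation (0.16), cartilage (0.11) and ribosomal (0.19) lists. The estrogen and androgen list passed fry (0.00745) but not camera.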

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

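Leaving out both libraries that stand apart, control replicate 2 and TWP 700 replicate 1, and removing a length trend were chosen after seeing the data. The counts of 1871 higher and 1731 lower genes stayed within 1.5 times under RLE scaling, upper quartile scaling, no filter, the stricter filter, DESeq2, limma-voom and the robust option off. Library totals gave 2809 higher and 868 lower genes, and 763 and 230 by 2-fold or more (the scaling moved the median gene). An adjusted p under 0.01 gave 796 and 692. Leaving out both libraries gave 2648 and 2606 genes. The samples kept were the most alike pair of each group, control replicates 1 and 3 (r = 0.988) and TWP 700 replicates 2 and 3 (r = 0.989). A smaller spread within groups thus goes with the larger counts, which are not stronger evidence. Other causes were not tested. Leaving out 1 sample gave 970 to 2063 higher and 896 to 1996 lower genes, and 405 to 622 and 288 to 358 by 2-fold or more, with fewer samples in each fit.

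The replicate numbers did not pair the samples: deviations from the group means correlated at -0.05, -0.10 and 0.03 between samples of the same number. With the number as a block, 1317 genes were higher and 1248 lower, and 487 and 311 by 2-fold or more.

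Of 124 named genes called, 88 passed the threshold under every alternative that gave a value. Values that changed sign were of results not called: cyp3a65 (-0.20 to 0.30 without 1 sample, -0.0912 without both libraries), mt-rnr1 (0.0209 with library totals, -0.66 to 0.11 without 1 sample) and mt-rnr2 (0.13 with library totals, -0.35 to 0.12 without 1 sample). The camera direction changed without control replicate 3 for the AhR list (adjusted p = 0.825; 0.76 to 0.938 without any 1 sample), p53 (0.573; 0.227 to 0.812) and myeloid markers (0.923; 0.262 to 0.923). It also changed without control replicate 2 for liver genes (0.429; 0.0867 to 0.656), and without both libraries for hair cells (0.956) and liver genes (0.143). The alternatives planned for normalized values were not run, since counts were used. Splitting the 6 samples 3 against 3 makes 10 splits, too few for a share under 0.05. The real split was 1 of 10 with counts as large, for each of the 4 counts, and the highest other split called 1 gene.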

Other observations

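Words in the gene descriptions of the deposited table were tested for enrichment among the called genes (hypergeometric test, 795 words per direction, Benjamini-Hochberg adjustment; genes are not independent). Most words that repeat the gene lists are left out here. Glucuronosyltransferase genes were enriched among the higher genes (17 of 40, where 3.15 were expected, adjusted p = 4.89e-07), although these genes share exons and their reads are hard to assign. This in part repeats the lists, since ugt1a1 is in the xenobiotic and thyroid lists. Solute carrier genes (61 of 417 with the word solute, adjusted p = 0.000129) and kinetochore genes (7 of 15, adjusted p = 0.00257) were also enriched among higher genes. Among lower genes, those with the words autophagy (9 of 27, adjusted p = 0.0126) and F-box (13 of 58, adjusted p = 0.022) were enriched.

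The 13 mitochondrial protein genes, a list written after their upper-case symbols were seen, lay higher in the leachate group: 6 rose and 0 fell (median log2 fold change 0.53, camera adjusted p = 4.86e-06, and adjusted p = 0.174 with an estimated correlation, over the 4 lists added). The number that rose was 3 without control replicate 1. ND1 (log2 0.84 ± 0.14, adjusted p = 0.0023) and ND5 (log2 0.76 ± 0.13, adjusted p = 0.00306) led them.

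Of the tests on the patterns that follow, those on the clock and the eye were chosen only after the result was seen. The fasting list was written before its members were looked at, but after other results of these data were seen. It is therefore not independent of the pattern it was set against.

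Clock genes of opposite phases moved in opposite directions. A single library is argued against, since with each library left out in turn the median of either limb kept at least 0.909 of its size. A candidate explanation is that the groups were collected at different times of day. Of 25 genes of the 2 limbs, 84% (21) went the way this needs, with exceptions such as nr1d4b (log2 -1.38). The limbs were grouped after the values were seen, so that share restates the pattern and does not test the explanation. An action of the leachate on the clock cannot be told apart from a difference in collection time, since 0 samples have a stated time of collection. Clock outputs among the other called genes would share the same doubt.

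Lens genes lay lower, and 18 of 40 photoreceptor genes fell. Loss of short genes is argued against, since the median log2 fold change of the lens list was -0.75 before and -0.76 after the length trend of each library was removed, with 26 and 32 genes that fell. A smaller share of all photoreceptor cells would by itself lower all of their genes, but 4 rose. These were arr3b (log2 0.95), pde6c (0.94), arr3a (0.75) and grk7a (0.40), the last pair named after their values were seen. The rule on such rises was set after they were seen, so it does not test this cause. A smaller share of 1 type of photoreceptor cell, or a smaller share beside other changes, stays open. Control replicate 2 and TWP 700 replicate 1 are argued against as the whole cause of the lens falls by the median of -0.48 without both. The 25 lens genes that then fell add little, since lower calls over all genes went from 1731 to 2606 in that fit. Without TWP 700 replicate 3, 9 lens genes fell. Lower expression within lens cells, a smaller lens, and a different age or time of collection were not tested and stay open.

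Proteasome genes, igfbp1b and bnip3 were higher in the controls than in the leachate group. A hypothesis is that the controls may have been in a more fasted state. In a list of 21 measured fasting and FoxO genes, 8 were lower in the leachate group and 0 higher, with a median log2 fold change of -0.33 (camera adjusted p = 9.38e-05, and adjusted p = 0.0591 with an estimated correlation), close to the bound of -0.3 set beforehand and short of it with library totals (-0.20, where the median of all genes was 0.131), without control replicate 2 (-0.29) and without control replicate 2 and TWP 700 replicate 1 together (-0.29). The camera values of this list were adjusted over the added lists only. These include the clock limbs, which were grouped after their values were seen. The adjusted p is therefore not comparable with that of the fixed lists. The muscle ubiquitin ligase genes trim63a (276 to 152 CPM, log2 -0.86) and fbxo32 (216 to 128 CPM, log2 -0.76) led the list, and the number that fell was 3 without control replicate 1, TWP 700 replicate 2 or TWP 700 replicate 3. Feeding, yolk reserves and the time of collection are not given in the labels, so an effect of the leachate on these genes stays open.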
